A study of Caenorhabditis elegans with 2 samples.

How the data were processed

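Chromatin bound by REF-2, a zinc finger transcription factor of the Zic family, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole *Caenorhabditis elegans* hermaphrodites at the late embryonic stage, 3 hours after synchronization by bleaching of eggs. The strain was OP520, which carries the unc-119(tm4063) mutation and an integrated transgene, wgIs520, that encodes REF-2 fused to a tag with green fluorescent protein. Per the labels, the immunoprecipitation used an antibody against green fluorescent protein and the chromatin was fragmented by sonication. The antibody field of the labels names the target protein rather than the tag. The labels give 1 group with 2 biological replicates. Nothing in them says whether the replicates were separate cultures.

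The authors deposited peak lists made on 2 builds of the genome, ce11 and ce10. For each build there was a relaxed list of 30000 peaks for each replicate, a relaxed list for the pooled replicates, and a shorter list thresholded on reproducibility between replicates (IDR), here called the optimal list. The labels name a possible control experiment. Per the deposited file list, each relaxed list derives from the alignments of its libraries and from 1 further file that the list does not describe, so whether peaks were called against the control was not given in the sources used here. The peak caller, the aligner and their versions were not given in the sources used here. The signal per peak is the authors' own value, taken from the deposited lists, and normalization of signal between lists was not given in the sources used here. The −log10 q per peak is likewise the deposited value, per the labels' file descriptions. The signal was used to rank and describe peaks within a list, and to set the replicates side by side at matched peaks. Read counts and coverage tracks were not analysed here, so the depth of each library is unknown. Control and untagged samples were not analysed here.

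Gene models and sequence came from WBcel235, the assembly called ce11 in genome browsers, and all coordinates are 1-based positions on it. The ce10 lists entered only counts, signal distributions and the comparison of replicates, with no conversion of coordinates. A promoter window ran from 1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding gene. A summit lying in several windows counted for each of those genes. The background for gene lists was the 19973 protein-coding genes on the 6 nuclear chromosomes.

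Replicates were compared as the share of the 2129 strongest peaks of replicate 1 with a summit within 200 bp of one of the 2129 strongest of replicate 2, set against 1000 circular shifts of the peaks along the joined chromosomes (one-sided). Log2 signal was compared at optimal peaks matched in both replicates, with bootstrap intervals from 1000 resamples. The share of peaks on X was tested with an exact binomial test (two-sided), and the share in promoter windows with 1000 circular shifts (two-sided). Positions in 7 classes of annotation were compared with 200 shifts, a split added after the data were seen. Each summit counted once, in the first class that held it. The order was promoter window, 5' UTR, coding exon, 3' UTR, noncoding gene exon, intron and intergenic. For 30 gene lists, 16 of named genes and 14 taken from gene name patterns, genes with a promoter peak were compared in and out of the list with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. For 7 classes of noncoding gene, the share with a summit within 200 bp was compared with 1000 circular shifts and adjusted over the classes. The Zic-type core CAGCRGG (R is A or G) and 11 other motifs were counted on either strand in windows centred on summits and in windows 1000 bp to each side. Summit windows were compared with the window on 1 side, drawn at random, by an exact test on discordant pairs (two-sided), and the printed flank share is the mean of both sides. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks and genes are not independent replicates, so p-values describe these lists and not the spread between samples.

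The lists, tests, windows, the rule for named genes and most alternatives were fixed before the data were examined. Named were the 25 optimal peaks with the highest signal, up to 4 members per gene list with a promoter peak and the highest signal, and always ref-2, unc-119, ttx-3 and lin-39. A peak was named by each gene whose promoter window held the summit, or otherwise by the nearest 5' end, said to be nearest. Alternatives covered leaving out each replicate (the 2129 strongest peaks of the other replicate in place of the optimal list), the stronger part of the optimal list, summit distances, promoter windows of 500 and 2000 bp, any transcript start, circular shifts and matched genes in place of Fisher's test, the nearest 5' end within 5000 bp, other flanks and windows, dinucleotide-shuffled sequence, the ce10 lists, and the removal of peaks within 20 kb of ref-2 and unc-119. For gene lists, a range of ratios over alternatives pools odds ratios with ratios of observed to expected genes from shifts and matched genes. A range of adjusted p over alternatives likewise pools Fisher and permutation p. Chosen after seeing the data were the removal of peaks near tRNA genes from the X share and, for the gene lists, the matching of promoter GC content, the removal of peaks near noncoding genes or near ref-2 and unc-119, and the assignment of each summit to 1 gene.

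Simulated data were used to try the tests of overlap, promoter share, gene lists, motifs, noncoding classes and X share. Where peaks were placed there were 2129 of them. Gene lists were tried on genes drawn at random and motifs on random sequence. The other statistics had no such trial. With 60% of peaks shared, the overlap test recovered 60.3%, and for independent lists it gave a permutation p = 0.921. A promoter share of 60.8%, worked out from the planted peaks and from shifts of the same simulated peaks, was recovered as 60.6%. A planted gene list was called, and in 3 of 100 runs without a planted list any list was called. Over 100 circular shifts of the real peaks the median number of lists called was 0 and the highest was 1. Shifted peaks reach 491 genes on average against 1257 for the real peaks, so fewer calls could arise there. The random draws took each gene independently, without shared promoters. Neither trial therefore gives the rate of false calls for the real peaks. A planted motif difference of 9.72 percentage points, worked out from the difference measured before planting, was recovered as 9.72. Both of these trials check the counting only. With summits planted at 200 tRNA genes, 218 tRNA genes were found near a summit and 0 other classes were called, and random peaks gave an exact p = 0.629 for the X share. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.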

Results

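REF-2 binding was measured by ChIP-seq against its green fluorescent protein tag in whole late embryos of 1 transgenic strain. REF-2 is a Zic-family zinc finger protein that acts in epidermal cells and in the specification of neurons. The samples formed 1 group of 2 biological replicates, so replicates could be compared with each other but not with another condition. Read depth per library is unknown. The optimal list on ce11 held 2129 peaks with a median signal of 145.7 (range 105.5 to 2351), and the −log10 q of these peaks ran from 0.954 to 2.87. The relaxed lists held 30000 peaks each, with a median signal of 25.9 in replicate 1, 30.4 in replicate 2 and 52.8 in the pooled list. The optimal peaks were the 2129 strongest of the pooled list by signal.

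The comparison of replicates asks whether both replicates marked the same places. The peaks upstream of K12H4.5 and M01F1.9 on chromosome III ranked first and second by signal in either replicate, and the rpl-3 peak ranked 3 in replicate 1 and 4 in replicate 2. Of the 2129 strongest peaks of replicate 1, 1505 (70.7%, 95% interval 68.7 to 72.6) lay within 200 bp of one of the 2129 strongest of replicate 2. Shifted peaks gave 0.835% on average and 1.60% at most (permutation p = 0.000999, the smallest the 1000 shifts can give). Signal at the 2112 optimal peaks matched in both replicates had a Spearman rho of 0.647 (bootstrap interval 0.617 to 0.675) and a Pearson r of 0.733 on the log2 scale, across peaks, which are not independent replicates. The optimal list is labelled as thresholded on reproducibility, but its peaks were exactly the 2129 strongest of the pooled list by signal. It thus holds peaks weak in 1 replicate, such as that of his-1 and his-2 (rank 1572 in replicate 1, 21035 in replicate 2). Pooled signal comes from these same replicates, so agreement at its peaks was still partly selected. Of the 2129 optimal peaks, 1494 (70.2%) matched the 2129 strongest of both replicates and 53 (2.49%) those of neither. At the 2112 matched peaks the median log2 ratio of replicate 2 to replicate 1 was 0.18. After centring on that median, 78 peaks (3.69%) differed by more than 2-fold, 41 higher in replicate 2 and 37 higher in replicate 1. Without centring, 92 differed, 75 higher in replicate 2 and 17 higher in replicate 1, and on ranks within each relaxed list 653 differed by more than 2-fold. No test applies to these differences, with 1 library on each side. Among the named peaks, the sel-12 promoter peak had a signal of 72.9 (rank 972) in replicate 1 and 42.9 (rank 5716) in replicate 2, and the sox-2 promoter peak ranked 4333 in replicate 1 and 1392 in replicate 2.

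**Figure D1:**
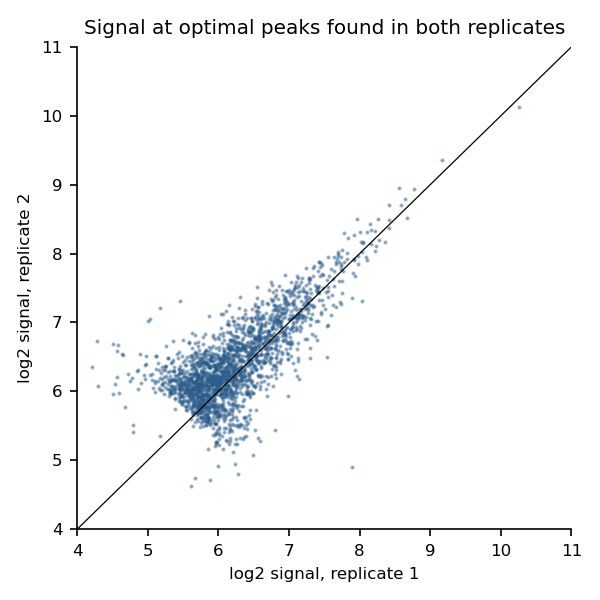
Log2 signal of replicate 1 (horizontal axis) and replicate 2 (vertical axis) at the 2112 optimal peaks found in both replicates. Each point is a peak and the line marks equal signal. The Spearman rho is 0.647.

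Of the 25 strongest peaks, 21 had a summit in a promoter window. The strongest, with a signal of 2351, had its summit on chromosome III at 8043960 (peak 8043780 to 8044163), at -527 bp from the 5' end of K12H4.5. The next was that of M01F1.9 (signal 1221, summit III 3500035, at -978 bp, inside the neighbouring gene M01F1.8). After it came rpl-3, which encodes a protein of the large ribosomal subunit (926, summit III 3867582, at -272 bp). Next were ftt-2, a 14-3-3 protein (878, X 11605994, at -575 bp), eel-1, a ubiquitin ligase (847, IV 3050658, at -554 bp), and the summit shared by sas-4, a centriole assembly factor, and F10E9.11 (808, III 8319283). The summit shared by K01G5.10 and tasp-1 followed (772), then the one between vps-51 and lin-35, the retinoblastoma-related repressor (757, I 5807475), and the one between his-67, his-68 and alg-5, a pair of histone genes and an Argonaute gene (677, I 9988938). Peaks at tos-1 (676), at ecps-1 and atx-2 (618), at cdc-48.1, a protein-unfolding ATPase (613), at rab-7, W03C9.5 and mex-1 (613), and at Y71G12B.30 and chaf-2 (609) came next in promoters. The others in promoters were Y39E4B.6 (597), ears-2 with uncp-18 (575), mlcd-1 with idhg-1 (573), the chemoreceptor gene sre-23 (559), prp-19 with K10D2.5 and emb-1 (554), bag-1 (551) and rpl-35 (551).

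Of these 25 peaks, 10 lay on chromosome III and 3 on X, and 6 lay within 200 bp of a noncoding gene. The 4 outside promoters included one in an exon of the snoRNA gene C51F7.4 (701, V 12303639, nearest F55C5.17) and one in an exon of a tRNA gene (553, X 12563806, nearest T24D5.1). The other 2 were intergenic, nearest C30E1.4 (617, X 16929791, 5855 bp from its 5' end) and nearest W03C9.1 (602, II 11960834, within 200 bp of a snoRNA gene). All 25 ranked at 33 or higher in replicate 1 and at 29 or higher in replicate 2. At 10 of the peaks the promoter windows of several genes overlapped, so the target gene was not resolved.

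Across 7 classes of annotation, a split chosen after the data were seen, summits were concentrated in promoter windows, in exons of noncoding genes and in 5' UTRs, and were sparse in coding exons and introns. Promoter windows held 972 of 2129 summits (45.7%, 43.5 to 47.8) against 21.5% of shifted summits (permutation p = 0.002, the smallest the shifts can give). Promoter peaks had a median signal of 154.0 and other peaks 138.0, and the median distance from a summit to the nearest 5' end was 946 bp. Each summit counted once, in the first class that held it, with promoter windows first. Of summits in no earlier class, exons of noncoding genes held 218 (10.2% of all summits against 2.65% when shifted), and 5' UTRs 30 (1.41% against 0.788%). Coding exons held 66 (3.10% against 19.7%), 3' UTRs 9 (0.423% against 2.35%), introns of protein-coding genes 393 (18.5% against 30.001%) and intergenic sequence 441 (20.7% against 23.1%). Adjusted permutation p was 0.0139 for promoter windows, both kinds of exon, 3' UTRs and introns, each from the smallest p that 200 shifts can give, and 0.0199 for 5' UTRs and intergenic sequence.

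**Figure D2:**
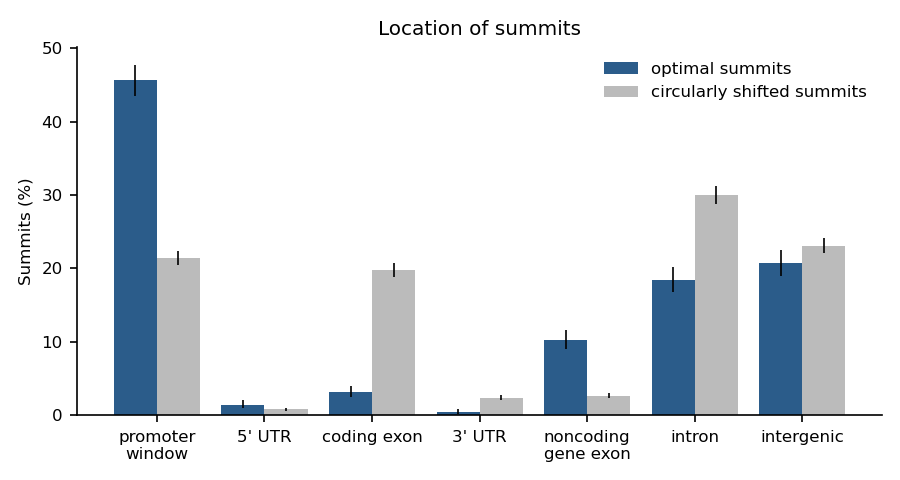
Share of the 2129 optimal summits (percent) in 7 classes of annotation, each summit in the first class that held it, beside the mean of 200 circular shifts. Error bars are 95% exact intervals for summits and SD over shifts for shifted summits; promoter windows hold 45.7%.

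Genes for ribosomal proteins, histones and the cell cycle had promoter peaks more often than other genes. In all, 1257 of 19973 protein-coding genes (6.29%) had one, and 11 of the 30 lists passed the threshold, 7 with peaks more often and 4 less often. Many members named below share their summit with the promoter window of another gene, which is not always named. Of 78 ribosomal protein genes, 38 had a promoter peak (48.7%, 37.2 to 60.3), with an odds ratio of 14.5 (9.05 to 23.4) and adjusted p = 4.58e-24 in Fisher's exact test. The strongest, with the pooled signal in brackets after each gene here and for the other lists, were rpl-3 (926), rpl-35 (551), rpl-15 (523) and rpl-20 (489). Of 72 histone genes, 20 had one (odds ratio 5.80, adjusted Fisher p = 1.1e-07), led by his-67 and his-68 (677) and by his-31 and his-32 (282). These 20 genes rested on 12 summits, since histone genes share promoters. Their share was 27.8% against 6.22% of other genes, and their number 1.92 times that expected among genes of the same promoter GC content (adjusted permutation p = 0.0224, over alternatives 5.70e-09 to 0.104) and 2.61 times that among genes of the same upstream intergenic length. With the nearest 5' end the odds ratio was 2.22 for histone genes and 5.61 for ribosomal protein genes, which had 9.46 without peaks near noncoding genes. Histone genes are also near-identical copies, and how reads mapping to several places were treated was not given in the sources used here, so their peaks are uncertain. Of 28 cell cycle genes, 8 had one (odds ratio 5.99, adjusted Fisher p = 0.00168), among them lin-35 (757), the cyclin-dependent kinase cdk-4 (200.4), the cyclin cye-1 (182) and efl-1 (175), an E2F-like factor whose peak also lay in the promoter window of fbxa-90. The cdk-4 peak also lay in the window of F18H3.1 and the cye-1 peak in that of pqn-21. Against circular shifts of the peaks neither the cell cycle list (adjusted permutation p = 0.136, over alternatives 0.000175 to 0.136) nor the histone list (0.104) passed.

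Heat shock, apoptosis, Wnt and proteasome genes also passed the threshold, under 10, 4, 6 and 3 of the 13 alternatives respectively. Of 22 heat shock protein genes, 6 had a promoter peak (odds ratio 5.60, adjusted Fisher p = 0.00819), with hsp-1 (434), hsp-3 (397), hsp-60 (389, a summit shared with Y22D7AL.10) and hsp-110 (152) the strongest. These 6 genes rested on 5 summits, and the list did not pass with 1 gene per summit (adjusted Fisher p = 0.0604, over alternatives 0.00124 to 0.234) or without peaks near noncoding genes (0.0716). Of 15 apoptosis genes, 4 had one (odds ratio 5.43, adjusted Fisher p = 0.0429), namely the engulfment gene ced-5 (195), the cell death inhibitor ced-9 (139), ces-2 (115) and the cell death activator egl-1 (115). The ced-5 summit also lay in the window of F01D4.5, and the ced-9 summit, at -984 bp, in those of jmjd-4 and mev-1. With 1 gene per summit the apoptosis list did not pass. The odds ratio of the apoptosis list was 2.42 without replicate 1, 3.597 without replicate 2 and 1.81 with the stronger part of the optimal list. Of 32 Wnt pathway genes, 6 had one (odds ratio 3.45, adjusted Fisher p = 0.0429), with mom-1 (212, within 200 bp of a tRNA gene), vang-1 (207), wrm-1, a beta-catenin (191), and mig-5, a Dishevelled protein (186), the strongest. The mom-1 summit also lay in the window of lev-9 and the mig-5 summit in that of cct-1. Without peaks near noncoding genes the odds ratio of the Wnt list was 1.92 (adjusted Fisher p = 0.374, over alternatives 0.0029 to 0.390). Of 33 proteasome genes, 6 had one (odds ratio 3.32, adjusted Fisher p = 0.0429), with rpn-3 (152, a summit shared with hsp-110), rpn-11 (150.3), pas-1 (146) and pbs-3 (141) the strongest. The odds ratio of the proteasome list was 2.17 without replicate 1 and 1.11 with the nearest 5' end.

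Chemoreceptor, F-box, C-type lectin and cytochrome P450 genes had promoter peaks less often. Of 1309 chemoreceptor genes, 6 had one (0.458%, odds ratio 0.0641, ratios over alternatives 0.0285 to 0.103, adjusted Fisher p = 3.10e-28), among them sre-23 (559, within 200 bp of a snoRNA gene), sre-1 (382), sri-5 (207) and str-12 (154). The summits of sre-1, sri-5 and str-12 were shared with B0495.9, rsr-1 and fbxa-153 respectively. Of 322 F-box genes, 6 had one (odds ratio 0.279, adjusted Fisher p = 0.00168), including fbxb-85 (221, a summit shared with hex-3), fbxa-90 (175), fbxa-153 (154) and fbxa-83 (137). Of 240 C-type lectin genes, 4 had one (odds ratio 0.25, adjusted Fisher p = 0.0057), namely clec-126 (222, beside tRNA genes), clec-140 (154), clec-104 (120) and clec-266 (119.4). Against circular shifts neither the F-box (adjusted permutation p = 0.234, over alternatives 6.28e-05 to 0.234) nor the C-type lectin list (0.234, over alternatives 0.00104 to 0.234) passed. Of 74 cytochrome P450 genes, 0 had one, with a 95% upper bound of 4.86% (adjusted Fisher p = 0.0429), and this list passed under 4 of the 13 alternatives, with odds ratios of 0.294 in the 2000 bp window and 0.467 at the nearest 5' end.

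The other 19 lists, which hold most of the neuronal and tissue genes, did not pass the threshold with the promoter window fixed beforehand. Body wall muscle genes and nuclear hormone receptor genes came closest. Body wall muscle genes had 6 of 35 (odds ratio 3.09, adjusted Fisher p = 0.0507), led by unc-112 (269), act-1 (154), pat-4 (140.0) and mlc-3 (126). Muscle genes passed under 5 of the 13 alternatives, among them the 2000 bp window (adjusted Fisher p = 0.0027, over alternatives 0.0027 to 0.723). Pan-neuronal effector genes (adjusted Fisher p = 0.0108, over alternatives 0.00179 to 0.871) and epidermal genes (0.0344, over alternatives 0.000872 to 1) also passed as having peaks more often with that window, collagen genes as having them less often (odds ratio 0.3495, adjusted Fisher p = 0.0317, over alternatives 0.0317 to 0.487), and Hox and cell fusion genes as having them more often with any transcript start (0.0141, over alternatives 0.000872 to 1). Nuclear hormone receptor genes had 8 of 269 (odds ratio 0.453, adjusted Fisher p = 0.0507), led by nhr-255 (265), nhr-48 (234.9), nhr-1 (200.6) and nhr-142 (184), and passed under 4 of the 13 alternatives, among them the 2000 bp window (adjusted Fisher p = 0.0078, over alternatives 0.0078 to 0.805). Axon guidance genes had 4 of 25 (odds ratio 2.84, ratios over alternatives 1.37 to 8.75, adjusted Fisher p = 0.137, over alternatives 1.82e-05 to 0.792), namely unc-73 (264), unc-76 (152), the semaphorin mab-20 (124) and the ephrin receptor vab-1 (106), and collagen genes 4 of 156 (odds ratio 0.390, adjusted p = 0.137), namely col-71 (203), col-185 (198.8), col-38 (143) and col-2 (143). Pan-neuronal effector genes had 3 of 24 (adjusted Fisher p = 0.334), namely syd-2 (305), unc-11 (128) and rgef-1 (116), and neuropeptide genes 5 of 140 (adjusted p = 0.370), led by ins-39 (209), flp-23 (157), flp-32 (109) and nlp-31 (107). Hox and cell fusion genes had 2 of 16 (adjusted Fisher p = 0.40), ceh-20 (165) and elt-6 (116), and pharyngeal genes 2 of 19 (adjusted p = 0.483), tbx-2 (144) and myo-1 (117). Epidermal genes had 3 of 32 (adjusted Fisher p = 0.589), dpy-10 (176), sym-1 (153) and elt-6 (116), germline genes 1 of 40 (adjusted p = 0.645), xnd-1 (174), and homeobox genes named ceh 5 of 63 (adjusted p = 0.717), led by ceh-38 (208), ceh-39 (198), ceh-20 (165) and ceh-74 (131). Neuronal fate factors had 2 of 42, the Groucho-type corepressor unc-37 (185) and sox-2 (107), Notch pathway genes 1 of 20, the presenilin sel-12 (114), and intestinal genes 1 of 24, the yolk protein gene vit-1 (182), each with adjusted Fisher p = 1. AIY interneuron genes (0 of 10, adjusted Fisher p = 1), glial genes (0 of 14, adjusted p = 1), bHLH genes named hlh (0 of 25, adjusted p = 0.549), neurotransmitter genes (0 of 29, adjusted p = 0.40) and major sperm protein genes (0 of 43, adjusted p = 0.210) had none.

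Without replicate 1, 7 lists passed, and the Wnt (adjusted Fisher p = 0.133, over alternatives 0.0029 to 0.390), apoptosis (0.356, over alternatives 0.0185 to 0.729), proteasome (0.248, over alternatives 0.0175 to 0.805) and cytochrome P450 lists (0.0853, over alternatives 0.0263 to 0.641) did not. Without replicate 2 the apoptosis list did not pass (adjusted Fisher p = 0.161) and the nuclear hormone receptor list did (0.0466, over alternatives 0.0078 to 0.805). Against circular shifts of the peaks only the ribosomal protein and chemoreceptor lists passed, each with adjusted p = 0.003 from the smallest permutation p that 10000 shifts can give. For the others the ratio to shifts stayed on the same side of 1, with 4.62 for cell cycle, 4.41 for histone, 4.25 for heat shock, 4.13 for apoptosis, 2.977 for Wnt, 2.92 for proteasome, 0.295 for F-box, 0.266 for C-type lectin and 0 for cytochrome P450 genes.

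**Figure D3:**
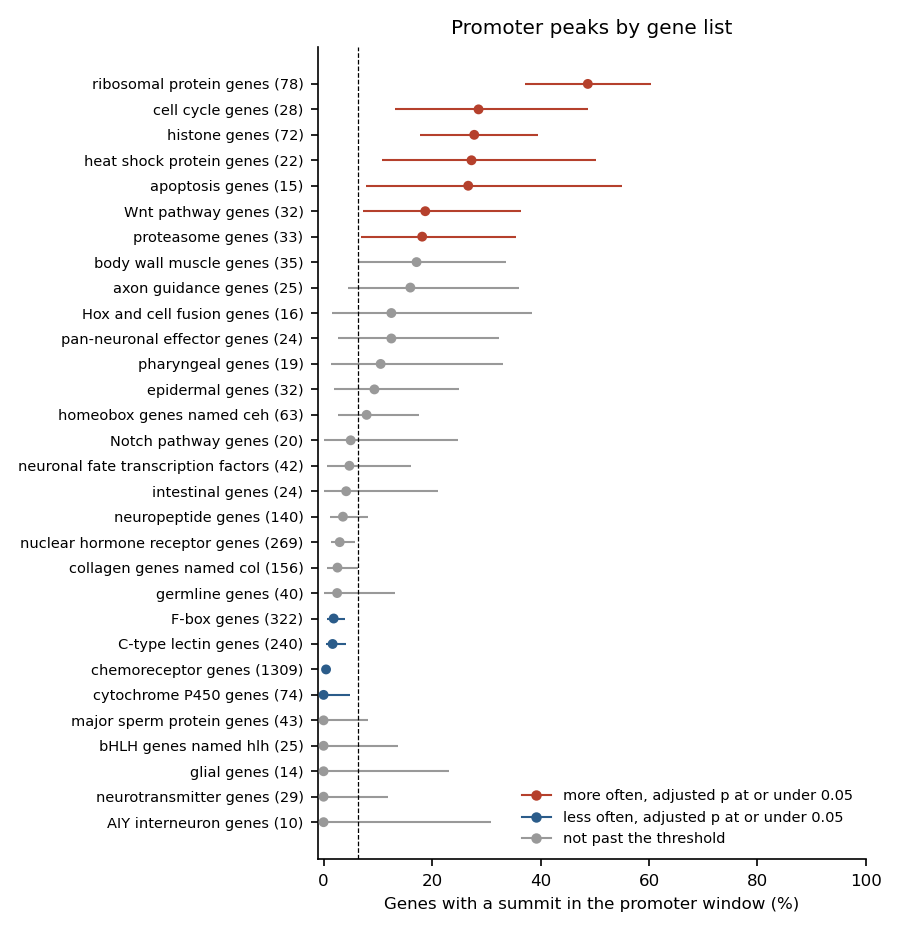
Percent of genes in each of the 30 lists with an optimal summit in the promoter window, with 95% exact intervals and the number of genes in brackets. The dashed line marks 6.29%, the share of all protein-coding genes; colours mark lists past the adjusted p threshold of 0.05.

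Genes for tRNAs and other small noncoding RNAs often had a summit beside them. Of 612 tRNA genes, 171 (27.9%, 24.4 to 31.7) had a summit within 200 bp, against 0.984% for shifted peaks. The shares were 69 of 346 for snoRNA genes (19.9% against 1.10%), 17 of 129 for snRNA genes (13.2% against 1.13%) and 604 of 7764 for other annotated ncRNA genes (7.78% against 1.15%). Each of these 4 classes had permutation p = 0.002, the smallest the shifts can give, and adjusted p = 0.0035. For miRNA genes 7 of 261 (2.68% against 1.02%, adjusted permutation p = 0.0839), for lincRNA genes 10 of 194 (5.15% against 3.23%, adjusted p = 0.224) and for rRNA genes 0 of 20 had a summit nearby (adjusted p = 1). With either replicate left out, miRNA genes passed the threshold (9 genes, adjusted permutation p = 0.0224 without replicate 1, and 10 genes, adjusted p = 0.0112 without replicate 2, over alternatives 0.0028 to 0.949). Without replicate 1 lincRNA genes passed too (13 genes, adjusted permutation p = 0.0256, over alternatives 0.0256 to 0.557).

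Peaks were more frequent on chromosome X than its length alone gives. X held 488 of 2129 optimal peaks (22.9%, 21.2 to 24.8), against 17.7% of the length of the 6 nuclear chromosomes (exact binomial p = 7.83e-10) and 13.7% of protein-coding genes. Chromosome X also held 276 of the 612 tRNA genes. The other chromosomes held 380 (I), 332 (II), 356 (III), 302 (IV) and 271 (V) peaks. Per megabase there were 27.5 peaks on X, 25.8 on III, 25.21 on I, 21.7 on II, 17.3 on IV and 13.0 on V.

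The Zic-type core was more frequent at summits than beside them. CAGCRGG, the core that vertebrate Zic proteins bind, lay in 141 of 2129 summit windows (6.62%, 5.60 to 7.76) and in 1.74% of flanking windows (exact p = 5.68e-18, adjusted p = 1.70e-17 over 12 motifs). Both forms were more frequent, CAGCAGG at 3.48% against 1.22% (adjusted exact p = 1.96e-06) and CAGCGGG at 3.24% against 0.517% (adjusted p = 6.85e-15), as was the extended CACAGCRGG at 0.892% against 0.141% (adjusted p = 0.00103). The Gli-type TGGGTGGTC was found in 0.329% against 0.0939% (adjusted exact p = 0.196). GAGAGAGA was more enriched than the core, in 13.4% of summit windows against 2.28% (adjusted exact p = 3.89e-42). GGGCGG was in 13.4% against 3.80% (adjusted exact p = 4.28e-31), a larger difference but a lower ratio than the core, and the E-box CAGCTG in 6.90% against 4.11% (adjusted p = 0.000296). The GATA motif WGATAR (24.9% against 36.4%, adjusted exact p = 1.24e-15), TTTTTTTT (9.25% against 21.9%, adjusted p = 1.25e-27) and TAATTA (5.21% against 9.11%, adjusted p = 1.96e-06) were less frequent at summits, and TGASTCA did not differ past the threshold (1.32% against 1.88%, adjusted p = 0.222).

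Summit windows were richer in G and C (47.03%) than flanking windows (36.7%). Among the 420 orders of the letters of the core, 45 of the 419 others (10.7%) had a summit-to-flank ratio as high. Of the 25 strongest peaks only that of sas-4 and F10E9.11 held the core, CAGCGGG on the plus strand at III 8319230 to 8319236, in the sequence ATAACCACAGCGGGGGGTAAC within the 5' UTR of F10E9.11. Among all the other named peaks, only those of the Wnt gene wrm-1 (CAGCAGG, minus strand, III 5722237 to 5722243, in GTTCAAACAGCAGGACGAACG) and of the muscle gene pat-4 (CAGCGGG, minus strand, III 95141 to 95147, in GCCTGGCCAGCGGGGGAACAA) held it. The core was in 46 of the 532 strongest optimal peaks (8.65%) and in 27 of the 532 weakest (5.08%), a difference of 3.57 percentage points (Fisher's exact p = 0.0284). That difference was 0.940 points without replicate 1 (Fisher's exact p = 0.655) and 1.69 points without replicate 2 (p = 0.338), so it did not pass the threshold in either replicate alone.

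**Figure D4:**
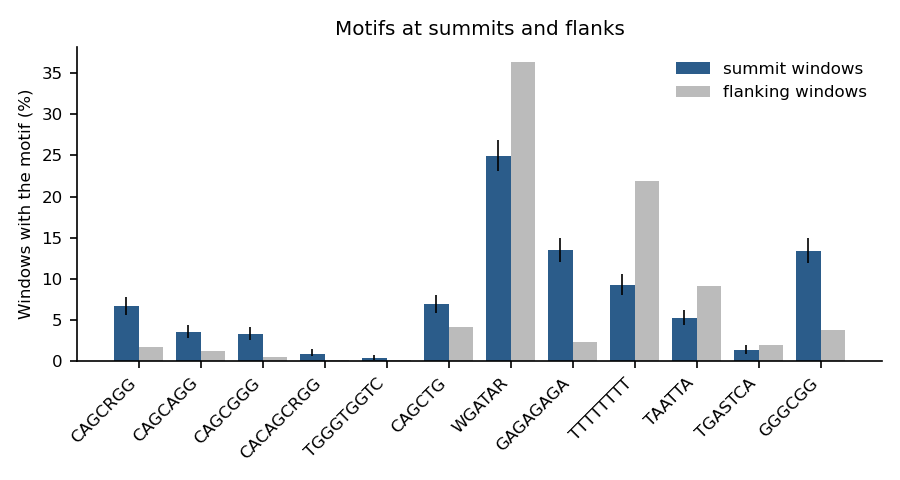
Percent of windows holding each of the 12 motifs at the 2129 optimal summits, with 95% exact intervals, and in windows 1000 bp to each side (mean of both sides). The core CAGCRGG is in 6.62% of summit windows and 1.74% of flanking windows.

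The ref-2 gene itself stood in a region of strong peaks. Within 20 kb of ref-2 (X 7744239 to 7750013, plus strand) lay 8 optimal peaks, 3 of them inside the gene. One summit was in an intron (X 7745608, signal 214), one in an exon of the ncRNA gene C47C12.9 inside ref-2 (X 7747350, signal 138) and one in the 3' UTR (X 7749559, signal 142). The strongest, with a signal of 371, was intergenic just downstream (X 7750306, 6067 bp from the 5' end), and no optimal summit lay in the ref-2 promoter window. The 4 others lay at spp-14 and vit-1, so the vit-1 promoter peak is 1 of this group. In the 40 kb centred on ref-2, the mean signal of the 16 relaxed pooled peaks was 120.02, at percentile 98.7 of such windows over all protein-coding genes (percentile 98.1 in each replicate). Because the strain carries extra copies of ref-2 in its transgene, signal from these copies and from the chromosomal gene cannot be separated in these lists.

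For unc-119, whose mutation marks the strain, 0 optimal peaks lay within 20 kb (III 10902641 to 10908935), and the mean signal of the 40 kb window stood at percentile 60.7. That percentile was 42.4 over 80 kb. The interneuron homeobox gene ttx-3 (X 11764456 to 11769378) had 1 optimal peak within 20 kb, in exons of a tRNA gene and an ncRNA gene 11527 bp past its 5' end (X 11757851, signal 177). The Hox gene lin-39 (III 7528641 to 7536632) had 2, one in its own 5' UTR (III 7534805, signal 137, 1827 bp past the gene's 5' end) and one at cux-7, C07H6.2 and lig-4 (III 7520859, signal 397).

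**Figure D5:**
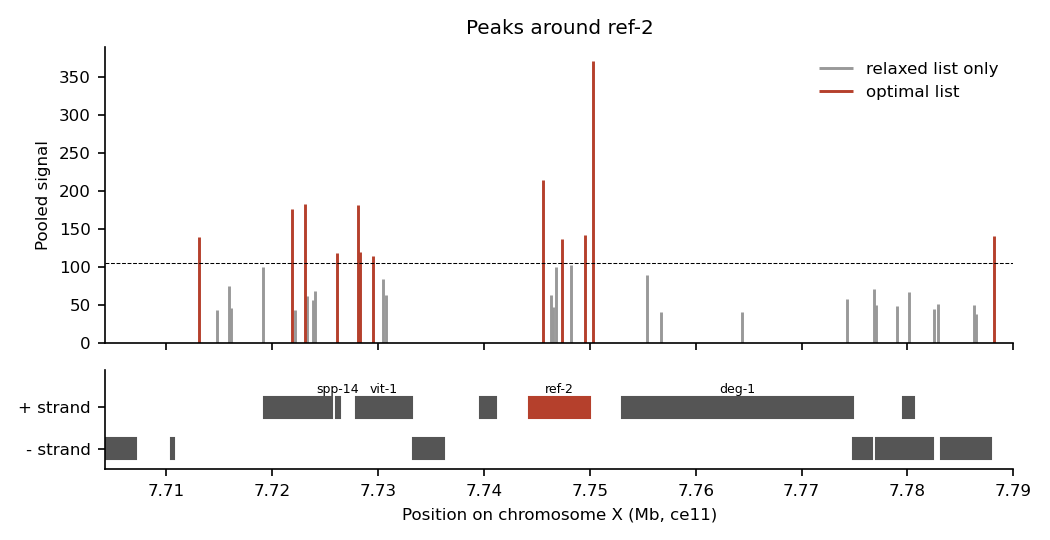
Pooled signal of relaxed and optimal peaks over 40 kb to each side of ref-2 on chromosome X (position in Mb, ce11), each line a summit, above the protein-coding genes of each strand. The dashed line marks the lowest optimal signal, 105.5; the tallest peak (371) lies just past the 3' end of ref-2.

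The ce10 optimal list held 2109 peaks with a median signal of 146.6, against 2129 and 145.7 on ce11. On ce10, X held 484 peaks, I 375, II 330, III 353, IV 299 and V 268. The overlap of replicates was 71.03% on ce10.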

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

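Of the tests in this part, those chosen only after results were seen are, for the X share, the removal of peaks near tRNA genes and, for gene lists, the matching of promoter GC content, 1 gene per summit, and the removal of peaks near noncoding genes or near ref-2 and unc-119. Replicate overlap (56.5 to 76.5%), the rank correlation of signal (0.646 to 0.666), the X share (21.1 to 22.9%), the promoter share (36.2 to 58.1%) and the excess of the Zic-type core (2.44 to 5.69 percentage points) kept their direction and, where tested, their side of the threshold under each alternative run. The number of noncoding classes past the threshold was 4 to 6, with miRNA genes passing when either replicate was left out and within 500 bp, and lincRNA genes without replicate 1 and within 500 bp. The X share was 21.1% without peaks near tRNA genes and 22.6% without peaks near ref-2 and unc-119. Read depth is unknown, so its limits cannot be stated. No paired analysis was possible because there is 1 group.

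Changed values follow, and the cause was not tested except where stated. By ranks, 653 peaks differed more than 2-fold between replicates, against 78 by signal. Against 11 gene lists, the number past the threshold was 7 without replicate 1 and 11 without replicate 2, 7 with the stronger part of the optimal list (fewer peaks), 7 with the promoter window of 500 bp, 7 with genes matched on GC content, 7 with 1 gene per summit and 2 with circular shifts, where shifted peaks reach 491 genes on average instead of 1257. With the 2000 bp window 15 passed and with the nearest 5' end 16. Without peaks near noncoding genes the Wnt, heat shock, proteasome and cytochrome P450 lists no longer passed. The core's difference between strong and weak peaks was 0.940 to 1.69 points with a replicate left out, 1.41 between the stronger and weaker parts of the list and 1.69 in a narrower window, none past the threshold. For ref-2 the signal percentile was 98.3 over 20 kb, 98.4 over 80 kb and 83.7 in the optimal list, where 50.5% of windows held no peak and ranked lowest. For unc-119 it was 82.2 over 20 kb and 42.4 over 80 kb, and the optimal list gave no value, with 0 peaks there. Ratios that crossed 1, none of them called in promoters, were those of Hox and cell fusion genes (0 with the 500 bp window), neuronal fate factors (1.12 with 2000 bp, 1.02 with any transcript start, 3.48 with the nearest 5' end, 1.01 with 1 gene per summit), epidermal genes (0.958 to 2.25 with a replicate left out), pharyngeal genes (0 with the stronger peaks), ceh genes (0.997 with 500 bp, 0.915 with 2000 bp), Notch genes (1.05 with 500 bp, 1.48 with any transcript start, 2.77 with the nearest 5' end, 1.07 with 1 gene per summit), glial genes (1.02 with any transcript start, 3.02 with the nearest 5' end), intestinal genes (1.10 with the stronger peaks) and AIY genes (1.23 with the nearest 5' end). Over all 30 lists and 390 values under alternatives, 312 kept direction and side, 42 were no longer past the threshold, 19 came past it without crossing 1, and 17 crossed 1. Of those 17, that of neuronal fate factors at the nearest 5' end also came past the threshold (adjusted Fisher p = 0.00464).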

Other observations

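The tests in this part chosen only after the result was seen are the search over all 8-base words, the comparison of 3 tissue lists with genes of matched length, the 100 shuffles of summit windows with their use against base composition, the GC matching of ribosomal protein genes, and both tests of the lists at nearest 5' ends. The X share was also examined without peaks near tRNA genes, a removal chosen after the result, without those near ref-2 and unc-119, a removal fixed beforehand, and by promoter. It is given only as values, which include 21.6% of promoter peaks and 24.0% of other peaks.

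Summits held a repeated sequence that was in none of the motifs fixed beforehand. Among 21345 words of 8 bases, 3188 were more and 2705 less frequent at summits than in flanks. Ordered by exact p, AGACGCAG came first with 296 of 2129 windows (13.9% against 1.34%), then GAGACGCA with 278 (13.1% against 1.15%). The words were compared only with flanks, which hold less G and C (36.7% against 47.03%). GAGACGCA lay a median of 41 bp from the summit, with 33.5% of its windows within 25 bp against 26.3% for uniform placement. GAGACGCA was in 2 of 161 summits near tRNA genes and in 14.02% of the others (Fisher's exact p = 3.62e-08). It was in 1 of 37 summits at ribosomal protein genes and in 3 of 4 at axon guidance genes, each a small number picked out after seeing the values. Whether a protein binds it is not known from these data.

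When each summit, in a promoter window or not, was given to the nearest 5' end within 5000 bp, 8 lists passed the threshold that had not passed at promoters, among them axon guidance genes with 11 of 25 (odds ratio 8.75) and Hox and cell fusion genes with 7 of 16 (8.64, ref-2 itself among them). The members, chosen after their values were seen, include the epidermal factor nhr-23 (signal 242, in the gene), egl-18 (160, at -1116 bp), egl-5 (145, at -1952 bp), lin-26 (135, at -3471 bp), unc-71 (170.2, at -2651 bp) and ets-5 (317, at -1156 bp). Epidermal genes had 10 of 32, pan-neuronal effector genes 8 of 24, muscle genes 9 of 35, neuronal fate factors 10 of 42, pharyngeal genes 5 of 19 and ceh genes 11 of 63.

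The lists at nearest 5' ends may reflect long intergenic sequence, which collects peaks by chance. Against genes matched on the length of sequence nearest to each gene, 5 of the 8 lists stayed past the threshold, and against circular shifts, which keep the clustering of peaks, 5 did, the same 5 lists (axon guidance, Hox and cell fusion, epidermal, pan-neuronal and muscle), with observed to expected ratios of 3.22 and 3.00 for axon guidance genes and 3.08 and 2.975 for Hox and cell fusion genes. Both results go against length or clustering as the whole cause for these lists. The Hox and cell fusion list passed with adjusted permutation p = 0.0238 against matched genes and 0.0378 against shifts. It counts ref-2 itself and was not rerun here without it. It also shares egl-18 and elt-6 with the epidermal list, so the lists are not independent. For neuronal fate factors, pharyngeal and ceh genes the lowest adjusted p against matched genes was 0.127 with ratios above 1, so length cannot be told apart from binding there. Open chromatin at these genes stays untested, peaks outside promoter windows were not tested apart from those inside, and that REF-2 acts on these genes is a hypothesis.

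Peaks at ribosomal protein genes could come from GC-rich promoters or from signal that any immunoprecipitation gives at highly transcribed genes. Among genes of the same GC content of the promoter window, the number with a peak was 5.43 times that expected, which goes against GC content as the whole cause. Signal at these promoters without the Zic-type core was the other explanation, and 2 of 37 summits there held the core (5.41%, 0.661 to 18.2). That interval holds both the flank share of 1.74% and the 6.64% of other summits, so such signal cannot be told apart from direct binding. With so few summits, and most other summits also without the core, the test had little power to separate them. Frequent summits at tRNA, snoRNA and histone genes, which are also highly transcribed, leave nonspecific signal open. Near tRNA genes 17 of 161 summits held the core (10.6%, 6.27 to 16.4), against 6.30% of other summits. Near snoRNA genes 7 of 70 did (interval 4.12 to 19.5%), against 6.51%, and at histone genes 0 of 12 (0 to 26.5%), against 6.66%. Each interval holds the share of other summits, so the core was not shown to be scarcer at these summits. The core therefore cannot tell direct binding from nonspecific signal there. Control and untagged samples were not analysed here, and no biological explanation was tested.

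The Zic-type core at summits could follow from the base composition of the summit windows. The test set beforehand came out on that side, since 10.7% of the other orders of its letters were as enriched, above the 5% taken as the sign of composition. It is set aside as the whole cause only by shuffles chosen after that result, in which windows with the same dinucleotide content held the core in 3.66% on average and 4.46% at most, below the 5.60% lower bound at summits, so composition may account for the rise from 1.74% to 3.66%. Promoter sequence in general goes against the values too, with the core in 1.399% of promoter windows without a relaxed peak against 6.48% (5.02 to 8.22) at promoter summits, though those windows have less G and C (33.7% against 45.4%). In the shuffle comparison 13 other orders, led by GRCGCAG, exceeded the core, so a direct contact of REF-2 with the core is a hypothesis and accessible chromatin or another protein stays open. With A for R, GRCGCAG and GACGCRG lie within the frequent word AGACGCAG, and GRGACGC and GAGRCGC within GAGACGCA. These are the highest orders both against flanks and against shuffles. Both counts of orders as high as the core, the 10.7% and the 13, therefore include this recurring sequence as well as composition.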
